A study of Homo sapiens with 8 samples.

How the data were processed

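RNA of the cytoplasm and of the chromatin fraction was sequenced in biological duplicates of the cell lines Epi and Mes, per the labels. Per the labels' protocols, cells were lysed in a hypotonic buffer with NP-40 to release the cytoplasm, and nuclei were then lysed in a buffer with urea and NP-40, with alpha-amanitin present to stop transcription, before RNA of the chromatin pellet was extracted. Per the submitters' processing notes the genome build was hg19 and the tools were TopHat2 2.0.6, HTSeq and DESeq2. Library strand, the filters on reads, the annotation and the total depth are not given in the sources used here.

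Files of 4 comparisons were used, for coding and non-coding genes in each fraction. Per the file headers they hold, for each gene, the authors' log2 fold change, an adjusted p-value and a group value for each line. The deposited log2 fold changes are Epi over Mes, as their signs against the group values show, and are given here as Mes against Epi. They were smaller in size than the log2 ratio of the group means in every gene with both means above 0, so they were shrunken by the authors. The smallest absolute log2 value was 1.0002 and the largest adjusted p-value deposited by the authors was 0.0499, so only called genes are in the files. The adjusted p-values were corrected by the authors over genes not used here, and no p-value was corrected again over a gene group. The group values are a signal in normalized reads, which the deposited columns give as means of 2 libraries without a spread. Coding and non-coding tables and the fractions were scaled separately by the authors.

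Each group mean was the average of 2 library values, each a whole number of reads divided by the library's size factor, and the 2 step sizes were solved from the low values. Over all tables, 100% of the means had exactly 1 pair of whole reads. The method was tested on simulated data, where it recovered 2000 of 2000 means, while 1963 of 1963 shifted means had no pair. Genes in both the coding and the non-coding table of a fraction gave equal reads in 47 of 47 cases in chromatin and 27 of 27 in cytoplasm, per line. Size factors lay between 0.796 and 1.27. The numbers 1 and 2 of the recovered libraries are arbitrary and could not be joined to the replicate numbers of the labels or across fractions, so no pairing was used. The chi-square per gene between the 2 libraries of a group was between 4.24 and 24.4, far above the value for sampling noise, so no pair was a library deposited more than 1 time.

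The design fixed before the data were examined assumed a table of reads per library and a count model. Because the files hold comparisons and group means of called genes, the authors' calls were described as deposited, and the tests the design named for such files were used. Gene groups were tested by a two-sided exact binomial test of direction against equal shares, for groups with at least 5 listed members in a fraction over both tables. Adjustment was by Benjamini-Hochberg over 25 tests. The difference between fractions was fitted with limma 3.58.1 in R 4.3.3 (limma-trend) on log2(normalized reads + 1) with 4 groups, an adjusted p threshold of 0.05 and no fold threshold. A fold change on this scale understates changes of low genes. On simulated reads this model called 88% of coding genes with a log2 difference of 1 and 100% of those with 2, and 1.05% of unchanged genes, over 1529 genes. For 680 non-coding genes the values were 83.8%, 100% and 0.749%. The simulated changes were planted only in genes with a mean of at least 100 normalized reads. The simulated lines had no other difference, and every gene had the same relative spread. These rates therefore do not cover changed genes with few reads, or genes that differ between the lines in both fractions, as the listed genes do. Other computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. With 2 libraries against 2 an exact permutation test cannot give a p under 0.333, so none was run on single genes.

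Named genes were chosen by a rule written before the data were examined. It took, per fraction and table, genes with a symbol that is not a clone name, the 6 coding genes with the largest log2 fold change in each direction at a mean of at least 100 normalized reads and the 4 non-coding genes at a mean of at least 20. For the difference between fractions and for the ranks it took 5 coding and 3 non-coding genes in each direction, and for each gene group up to 4 called members with the largest change. CDH1, EPCAM, VIM, CDH2, ZEB1, ZEB2, SNAI2, FN1, HOTAIR, MALAT1 and NEAT1 were always looked up, and Y-linked genes and the X inactivation transcript were never named. Members of a group named beyond this rule were chosen after their values were seen, and some members that the rule takes are not reported here. In the coding table of each fraction 6 symbols had been turned into dates by a spreadsheet and were left without a name. Gene names are those of the files. Only RefSeq and GENCODE annotation of a later build was at hand, so it served for names, gene types and neighbours, and no coordinates are given.

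Alternatives were a stricter adjusted p of 0.01, a level minimum of 100 normalized reads, pseudocounts of 0.5 and 10, limma without a trend, a log2 difference of at least 1, and leaving out each library in turn. They were chosen before the data were examined, except for 1 use of the stricter adjusted p named next. Limma on the recovered libraries of each table, a minimum of 10 normalized reads in every library, a restriction to genes with reads in both lines in both fractions, an adjusted p of 0.01 in both fractions for the share of genes going the same way, a test of the groups against the share of the tables, changes to the members of groups drawn up afterwards, and levels and ranks of each line alone were added after the data were seen. A fold against a group without reads is a lower bound against 3 reads over the group. Intervals of shares are 95% exact Clopper-Pearson intervals and cover counting error only.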

Results

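Chromatin-associated RNA and cytoplasmic RNA were sequenced from 2 human cell lines derived from HEK (human embryonic kidney) cells and named Epi and Mes in the labels. Chromatin-associated RNA is enriched for transcripts that are still attached to the DNA they are made from, whereas the cytoplasmic fraction is enriched for mature RNA. How pure the fractions were was not tested. Biological duplicates of each line and fraction gave 8 libraries in 4 groups of 2. The deposited tables hold only genes that the authors called different between the lines, with an absolute log2 fold change of at least 1 and an adjusted p under 0.05, split into coding and non-coding genes for each fraction. A gene missing from a table was therefore either not called or not tested, and these cases were not distinguished here. Each group is given as the mean of its libraries in reads divided by a size factor, here called normalized reads. The reads behind each mean were worked out per library, and the chromatin libraries held between 1494192 and 2936790 reads in the listed coding genes against 5460262 to 6567308 in the cytoplasm libraries. These sums cover listed genes alone, so the full depth of each library is unknown. All counts of genes cover the rows used here. Fold changes are given as Mes against Epi.

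The first comparison asked which genes differed between the lines in chromatin-associated RNA. Among coding genes the largest excess in Mes was that of PIEZO2, a mechanically gated ion channel, at 12423 normalized reads in Mes (11853 and 12993 in its libraries) and 7.9 and 15.0 in the Epi libraries, a log2 fold change of 9.63 in the authors' deposited table with an adjusted p listed as 0. C5orf17 had 1366 normalized reads in Mes and no read in either Epi library, which is at least 1032-fold higher against a floor of 3 reads over the group, with an adjusted p of 1.31e-79 in the authors' deposited table. LRRC7, a synaptic scaffold gene, reached 932 against 0.395, and the zinc finger genes ZNF667, ZNF439 and ZNF69 reached 949 against 0.79, 1246 against 2.98 and 1501 against 4.69 normalized reads. Their log2 fold changes in the authors' deposited table were 7.89, 7.78, 7.58 and 7.57. In the other direction, PPP1R9A, an actin-binding scaffold gene, had 2270 normalized reads in Epi against 1.26 in Mes, a log2 difference of 8.61 towards Epi in the authors' deposited table with an adjusted p of 7.18e-96. FAM49A had 3171 in Epi against 5.53 in Mes and GALNT3, which starts mucin-type O-glycosylation, had 1919 against 2.14. UGT2B7, a glucuronosyltransferase of liver and kidney, had 1039.7 in Epi against 0.503 in Mes. PAX2, a transcription factor of kidney development, and CSRNP3 had 901 and 774 normalized reads in Epi and none in Mes, at least 538-fold and 462-fold higher in Epi against the same floor. The chromatin table held 2124 coding genes, of which 888 were higher in Mes and 1236 were higher in Epi. In each of these genes the 2 Epi libraries and the 2 Mes libraries did not overlap, which chance alone gives in 33.3% of genes, and the listed genes had been selected for a difference. The median absolute log2 ratio between libraries of a line was 0.09 in Epi and 0.17 in Mes over listed coding genes with a mean of at least 100 normalized reads.

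Gene groups fixed before the data were examined were counted over the chromatin tables, with a two-sided exact binomial test of direction and Benjamini-Hochberg adjustment over 25 such tests in both fractions. The test counts the members of a group as independent, so its p-values are too small where members change together. Of 48 epithelial junction, keratin and epithelial regulator genes, 14 were higher in Epi and 2 were higher in Mes (exact binomial test, adjusted p = 0.0261). They included the tight junction gene CLDN1 at 1555 normalized reads in Epi against 70.0 in Mes, MAP7 at 161 against 5.53, the integrin gene ITGB6 at 2626 against 229.8 and EPCAM, an epithelial adhesion gene, at 95.4 against 8.92. The log2 differences towards Epi were 4.38, 4.19, 3.48 and 2.98 in the authors' deposited table. CLDN4 and DSP were the 2 members higher in Mes. With members of at least 100 normalized reads alone, the adjusted p of this group was 0.0752. All 16 listed interferon-stimulated genes were higher in Epi (exact binomial test, adjusted p = 0.000763), among them XAF1 at 322 normalized reads against 4.27, the antiviral enzyme gene OAS1 at 77.1 against 2.26, the immunoproteasome gene PSMB9 at 238 against 24.1 and IFI44L at 86.4 against 7.54. Mesenchymal regulators and cytoskeleton genes went both ways, with 10 higher in Mes and 5 higher in Epi (exact binomial test, adjusted p = 0.629). The Mes side included TWIST2 at 37.5 normalized reads against 0.5 in Epi, GREM1 at 9988 against 1569, TGFB2 at 8595 against 1384 and SNAI2 at 101 against 38.2. ZEB1, CDH2 and MMP2 were higher in Epi, by 1.13, 1.05 and 3.10 on the log2 scale in the authors' deposited table. ZEB2 and VIM were not listed in any of the tables.

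Collagen and extracellular matrix genes were split in chromatin, with 5 higher in Mes and 7 higher in Epi (exact binomial test, adjusted p = 1). FBLN2 had 124 normalized reads in Mes against 3.98 in Epi, whereas VCAN had 7505 in Epi against 234 in Mes and the microfibril gene MFAP2 had 1187 in Epi against 29.8 in Mes. FBLN5 had 212 in Epi against 33.2 in Mes. Among renal developmental and tubule genes 6 were higher in Epi and 3 were higher in Mes (adjusted p = 0.846, exact binomial test). PAX2, LHX1 at 337 normalized reads against 16.8 and CDH16 at 67.0 against 1.63 were on the Epi side, and OSR1 at 71.9 in Mes against 7.27 in Epi was on the Mes side. Of the HOX cluster coding genes 9 were higher in Epi and 6 were higher in Mes (exact binomial test, adjusted p = 0.949). The 6 on the Mes side were all of the HOXC cluster, with HOXC13 at 183 normalized reads in Mes and no read in Epi, and the Epi side held HOXA, HOXB and HOXD genes such as HOXA7 at 229.98 against 36.3, HOXD1 at 67.6 against 12.8 and HOXD3 at 993 against 238. Cytosolic ribosomal protein genes had 4 listed members, too few for a test and all higher in Epi, among them RPL18 at 4117 normalized reads against 2005 and RPS16 at 2157 against 1053. The 2 listed cell cycle genes, AURKA and CCND1, were not tested as a group and were higher in Mes by 1.68 and 1.58 on the log2 scale in the authors' deposited table. Immediate-early and short-lived transcripts had 5 members on each side (exact binomial test, adjusted p = 1), with DUSP2 higher in Mes and DUSP6, NR4A2 and KLF4 higher in Epi by 2.28, 1.99 and 1.75 on the log2 scale in the authors' deposited table. Of the very long genes 6 were higher in Mes and 2 were higher in Epi (exact binomial test, adjusted p = 0.629), with SDK1 at 5317 normalized reads in Mes against 313 in Epi, NRXN3 at 6824 against 707, NPAS3 at 32.7 against 0.895 and, on the Epi side, MACROD2 at 331 in Epi against 45.0 in Mes. No mitochondrially encoded protein gene was listed in either fraction.

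Non-coding RNAs also differed in chromatin. LINC00670 had 928 normalized reads in Mes against 1.63 in Epi, a log2 fold change of 7.94 in the authors' deposited table with an adjusted p of 2.5e-59. The pseudogenes ZNF826P, RSL24D1P8 and ZNF702P had 279, 270.5 and 355 normalized reads in Mes, with log2 fold changes of 7.25, 7.22 and 6.83 in the authors' deposited table and no read in Epi for ZNF826P and RSL24D1P8. On the Epi side LINC00478 had 2038 normalized reads against 29.1 in Mes, the ribosomal protein pseudogene RPS20P20 had 219 against 1.57, BACE2-IT1 had 149 against 0.596 and LINC00340 had 135 against 1.08, with log2 differences of 5.98, 5.96, 5.94 and 5.54 in the authors' deposited table. HOTAIR, a long non-coding RNA of the HOXC cluster, had 928 normalized reads in Mes against 137 in Epi, and HOTTIP of the HOXA cluster had 30.6 against 1.92. HOXC-AS5 had 71.3 in Mes and no read in Epi, and HOXB-AS3, which is in the coding table, had 255 in Epi against 26.5 in Mes. HOX cluster non-coding RNAs numbered 5 on the Mes side and 4 on the Epi side (exact binomial test, adjusted p = 1). Among nuclear-retained long non-coding RNAs 3 were higher in Mes and 5 were higher in Epi (exact binomial test, adjusted p = 1). NEAT1, the scaffold of paraspeckles, had 362024 and 343167 normalized reads in the Mes libraries against 138985 and 121863 in the Epi libraries, and the telomerase RNA TERC had 168 in Mes against 1166 in Epi. PCAT1 had 7.58 in Mes against 27.7 in Epi. MALAT1 was not listed in any table. Cytoplasm-abundant long non-coding RNAs numbered 4 on the Epi side, including the signal recognition particle RNA gene RN7SL2 at 119999 normalized reads against 29422, RN7SL1 at 46.2 against 11.7 and LINC00493 at 332 against 156, and 1 on the Mes side, H19 (exact binomial test, adjusted p = 0.721). Non-coding RNAs linked to epithelial or mesenchymal states numbered 3 on the Mes side and 2 on the Epi side, MIR31HG and LINC00312 (exact binomial test, adjusted p = 1). The chromatin table held 1660 non-coding genes, 765 higher in Mes and 895 higher in Epi. With limma on the recovered libraries these counts turned to 621 and 588 without the first Epi library and to 646 and 598 without the second, an alternative added after the data were seen. SNORD3A, a small nucleolar RNA, made up 45.4% of the listed non-coding normalized reads in Epi and 28.3% in Mes, and NEAT1 made up 5.71% and 27.7%. Whether reads were counted by strand is not given in the sources used here, so reads of an antisense RNA and its partner cannot be told apart.

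The same comparison was made in cytoplasmic RNA. PIEZO2 again had the largest log2 fold change on the Mes side, at 10638 normalized reads against 0.882 and 10.92 in the authors' deposited table. INHBB, which encodes an activin subunit, had 4076 normalized reads in Mes against 6.61 in Epi, HOXC13 had 1199.6 against 0.44, RAI2 had 1479 against 3.96, C5orf17 had 782 against no read and ZNF415 had 612 against no read. On the Epi side FAM49A had 7264 and 7609 normalized reads in the Epi libraries against 2.15 and 2.37 in the Mes libraries, a log2 difference of 9.93 in the authors' deposited table with an adjusted p of 1.2e-156. GALNT3 had 3225 in Epi and no read in Mes, at least 1907-fold higher in Epi against a floor of 3 reads. ELTD1, an adhesion receptor gene, had 2132 against 1.13, DCDC2 had 3189.7 against 4.41, LRCH2 had 1621 against 1.67 and UGT2B7 had 1582 against no read. The cytoplasm table held 2314 coding genes, of which 1168 were higher in Mes and 1146 were higher in Epi. With limma on the recovered libraries the order of these counts turned when either Mes library was left out, an alternative added after the data were seen. The Epi and Mes libraries did not overlap in any of these genes, and the median absolute log2 ratio between libraries of a line was 0.15 in Epi and 0.12 in Mes.

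Mesenchymal regulators and cytoskeleton genes were mostly higher in Mes in cytoplasm, with 17 on the Mes side and 2 on the Epi side (exact binomial test, adjusted p = 0.00911). TWIST2 had 68.0 normalized reads in Mes against 0.879 in Epi, GREM1, a secreted BMP antagonist, had 65736 against 5735, TGFB2 had 27024 against 2435, the protease inhibitor gene SERPINE2 had 1462 against 227 and SNAI2 had 454 against 147. MMP2 and TGFBR2 were the 2 members higher in Epi, by 2.29 and 1.69 on the log2 scale in the authors' deposited table. Collagen and extracellular matrix genes were also mostly higher in Mes, with 18 on the Mes side and 5 on the Epi side (exact binomial test, adjusted p = 0.0443). FN1, encoding fibronectin, had 290128 normalized reads in Mes against 63594 in Epi, COL5A2 had 46793 against 5184 and FBLN2 had 456 against 2.2. MFAP2 and VCAN were higher in Epi, at 1657 against 48.4 and 6646 against 298 normalized reads. Interferon-stimulated genes numbered 18 on the Epi side and 3 on the Mes side (exact binomial test, adjusted p = 0.0124). IFI27 had 7676 normalized reads in Epi against 305 in Mes, XAF1 had 263 against no read, OAS1 had 118 against 6.19 and PSMB9 had 1222 against 113, and the members higher in Mes were RSAD2, HLA-C and HLA-B. All 8 listed cytosolic ribosomal protein genes were higher in Epi (exact binomial test, adjusted p = 0.0391), among them RPSA at 14072 normalized reads against 5438, RPL23A at 8804 against 3457 and RPL34 at 11745 against 5628. Reads of ribosomal protein genes can be shared with their many pseudogenes, so these values are uncertain.

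Epithelial genes numbered 12 on the Epi side and 4 on the Mes side in cytoplasm, which did not pass the test (exact binomial test, adjusted p = 0.24). MAP7 had 282 normalized reads in Epi against 7.86 in Mes, ITGB6 had 1519 against 95.0, the splicing regulator gene ESRP2 had 612 against 37.8 and EPCAM had 229 against 32.6. CDH1, encoding E-cadherin, was among the 4 genes higher in Mes, with CLDN4, DSP and JUP. CDH1 had 53.8 normalized reads in Mes and 12.8 in Epi, a log2 fold change of 1.65 in the authors' deposited table with an adjusted p of 0.00227, and it was not listed in chromatin. Renal genes numbered 5 on the Epi side and 4 on the Mes side (exact binomial test, adjusted p = 1), with PAX2 at 345 normalized reads in Epi and none in Mes, LHX1 at 464 against 33.1, CDH16 at 50.6 against 2.26 and OSR1 at 67.2 in Mes against 1.76 in Epi. HOX coding genes numbered 13 on the Epi side and 5 on the Mes side (exact binomial test, adjusted p = 0.267), with HOXD4 at 1520.5 in Epi against 257 in Mes, HOXD3 at 386 against 63.6 and HOXC11 at 762 in Mes against 139 in Epi. Beside HOXC genes the Mes side held HOXA2, at 139 normalized reads in Mes against 30.4 in Epi. The 5 listed cell cycle and DNA replication genes were higher in Mes (exact binomial test, adjusted p = 0.223), with the proliferation marker MKI67 at 67413 normalized reads against 29939, MCM3 at 16084 against 7028, CCND1 at 6081 against 1574 and AURKA at 16571 against 6365. Immediate-early genes numbered 9 on the Mes side and 4 on the Epi side (exact binomial test, adjusted p = 0.629), among them DUSP2 at 83.7 against 5.28, EGR3 at 47.0 against 3.96, NR4A3 at 189 against 39.6 and PIM1 at 3006 against 697 in Mes against Epi. Very long genes numbered 6 on the Mes side and 4 on the Epi side (exact binomial test, adjusted p = 1), with SDK1 at 2248 in Mes against 101 in Epi, NRXN3 at 4532 against 349, NAV2 at 6029.7 against 1105 and MACROD2 at 7.21 against 2361.

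Among non-coding genes in cytoplasm the pseudogene ZNF702P had 764 normalized reads in Mes against 0.882 in Epi, and HOXC-AS5, ZNF826P and LINC00670 had 251, 206 and 171 in Mes with no read in Epi. LINC00478 had 639 in Epi against 3.89 in Mes, PVRL3-AS1 had 1619 against 23.2, and MAL2, listed in the non-coding table, and FABP5P7 had 144 and 129.9 in Epi with no read in Mes. Their log2 differences towards Epi were 6.56, 5.93, 5.77 and 5.62 in the authors' deposited table. HOX cluster non-coding RNAs numbered 5 on the Mes side and 2 on the Epi side (exact binomial test, adjusted p = 0.809), with HOTAIR at 1036 normalized reads against 139 and HOXC-AS3 at 221 against 11.9 in Mes, and HOXB-AS3 at 773 in Epi against 86.2 in Mes. Nuclear-retained long non-coding RNAs numbered 3 on the Mes side and 2 on the Epi side (exact binomial test, adjusted p = 1), with NEAT1 at 30092 in Mes against 9290.4 in Epi and TERC at 179.6 against 1162. HOTTIP, on the Mes side, had 16.5 and 17.6 in the Mes libraries and a mean of 0.889 in Epi. TERC differed between its Epi libraries, at 1712 and 611 normalized reads. Fewer than 5 members of the other fixed non-coding groups were listed, so they were not tested. Of cytoplasm-abundant long non-coding RNAs, SNHG5, GAS5 and LINC00493 were higher in Epi, by 1.44, 1.30 and 1.02 on the log2 scale in the authors' deposited table, and H19 was higher in Mes by 2.71. Of RNAs linked to epithelial or mesenchymal states, HOTAIR, H19 and LINC00472 were higher in Mes and LINC00511 was higher in Epi. The table held 1060 non-coding genes, 466 higher in Mes and 594 higher in Epi.

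Markers of other cell types were sparse and went both ways. Of 13 endothelial markers, CDH5 was higher in Mes, at 14.0 normalized reads against 1.4 in chromatin and 37.2 against 1.76 in cytoplasm, and TIE1 was higher in Epi, at 36.7 against 3.77 in chromatin and 32.1 against 6.19 in cytoplasm. Of 15 leukocyte markers CD14 alone was listed, higher in Mes at 44.2 normalized reads against 12.7 in chromatin and 232 against 19.4 in cytoplasm. Of 20 neuronal and neural crest markers, 2 were higher in Epi and 1 was higher in Mes in chromatin, and 3 were higher in Epi and 2 in Mes in cytoplasm (exact binomial test in cytoplasm, adjusted p = 1). SNAP25 had 63.9 normalized reads in Mes and no read in Epi in chromatin, while MAP2 had 50.4 in Epi against 4.4 in Mes and NRCAM had 42.0 against 5.91. NEFL, in the non-coding table, had 13.2 in Epi and no read in Mes in cytoplasm.

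**Figure D1:**
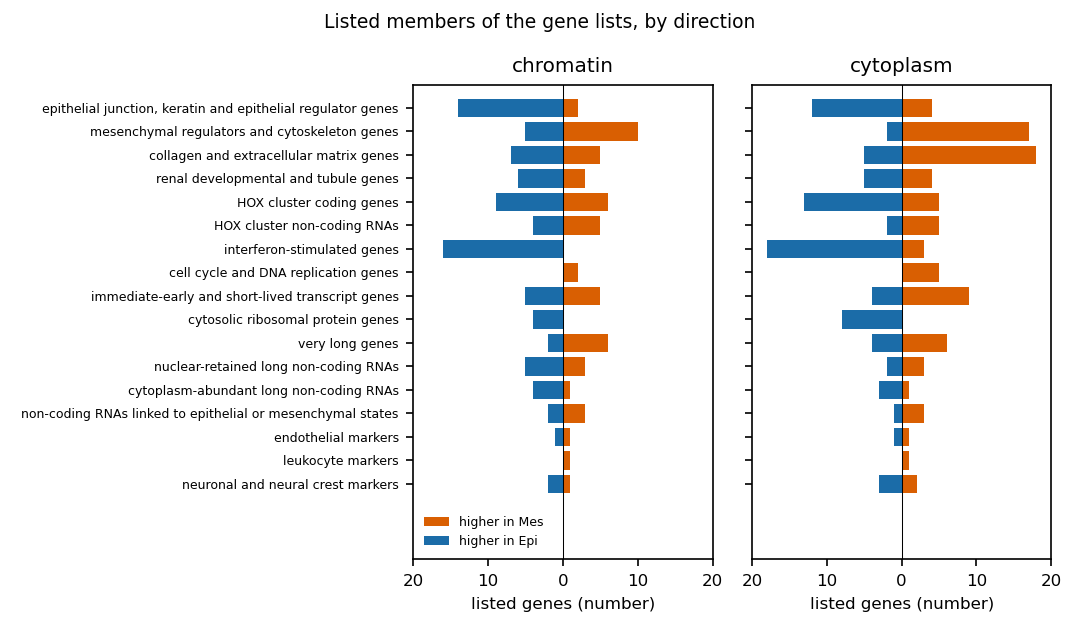
Number of listed members of each gene group fixed before the data were examined, for chromatin (left) and cytoplasm (right). Bars to the right of 0 count genes higher in Mes and bars to the left count genes higher in Epi. Interferon-stimulated genes lie on the Epi side in both panels (16 of 16 and 18 of 21), and mesenchymal genes lie on the Mes side in cytoplasm (17 of 19).

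**Figure D2:**
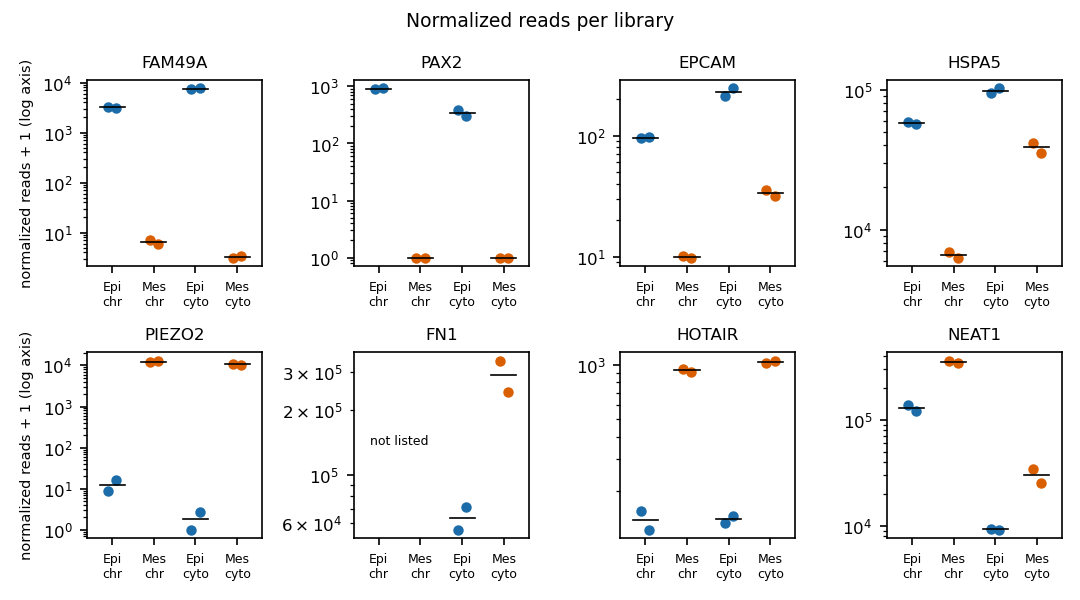
Normalized reads plus 1 per library on a log axis for 8 genes, with 2 Epi (blue) and 2 Mes (orange) libraries in chromatin (chr) and cytoplasm (cyto), and a line at each group's mean. Fractions were scaled separately, so heights compare within a fraction. FN1 was not listed in chromatin, and HSPA5 shows a wider gap between the lines in chromatin (57598 against 6598) than in cytoplasm (97912 against 38582).

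The next comparison asked whether the lines differed the same way in both fractions. Of the genes listed in both, all 1529 coding genes went the same way in chromatin and in cytoplasm, 644 higher in Mes and 885 higher in Epi, which is 100% with a 95% exact interval from 99.8% to 100%. Of 680 non-coding genes, 678 went the same way and 2 went opposite ways, 99.7% with an exact interval from 98.9% to 100%. The exceptions were RP11-146N23.1, named after its values were seen, with 41.1 normalized reads in Mes against 6.61 in Epi in chromatin but 8.05 against 2947 in cytoplasm, and J01415.5, with 95.2 against 213 in chromatin and 254 against 111 in cytoplasm. Across genes the log2 fold changes of the authors' deposited tables correlated between fractions with Pearson's r = 0.97 and Spearman's rho = 0.95 for coding genes and r = 0.94 and rho = 0.94 for non-coding genes. Genes are not independent replicates, and the tables leave out changes under 1, which sets the signs apart. Carry-over of RNA between the fractions was not tested and could raise this agreement. Genes listed in both fractions made up 72.1% of the chromatin list and 66.1% of the cytoplasm list for coding genes, but 41.0% of the chromatin list and 64.2% of the cytoplasm list for non-coding genes, with 980 non-coding genes in the chromatin table alone. A gene listed in a single fraction is not shown to differ between fractions.

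**Figure D3:**
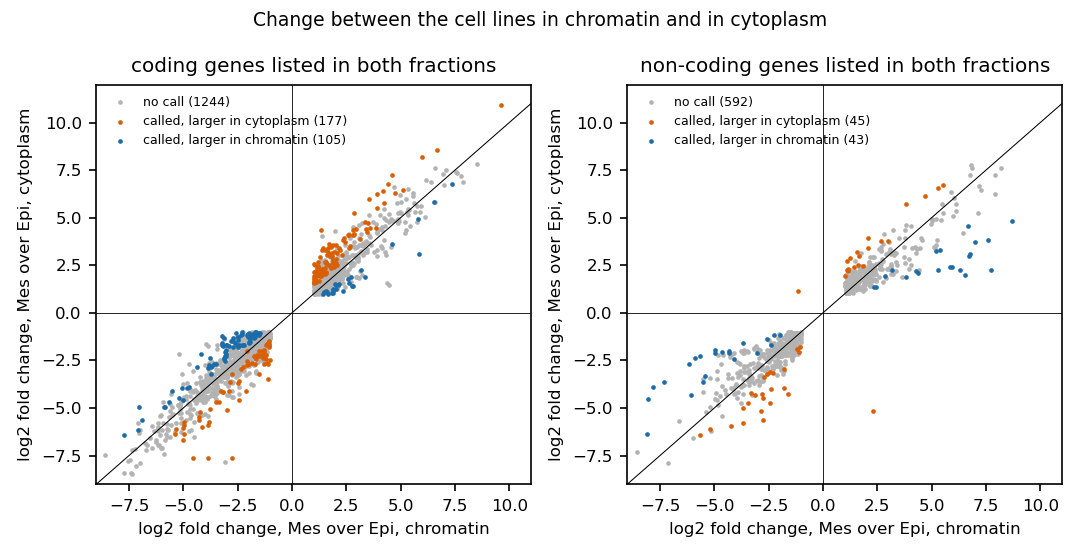
Log2 fold change of Mes over Epi in chromatin (horizontal axis) against cytoplasm (vertical axis), from the authors' deposited tables, for coding genes (left) and non-coding genes (right) listed in both. Each point is a gene, the diagonal marks equal change, and colours mark genes whose change differed between fractions by limma (adjusted p under 0.05). Genes that were never named are left out. Points of coding genes lie at the lower left and the upper right, and 2 non-coding genes lie outside them.

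The size of the change was then compared between fractions in a limma model on log2(normalized reads + 1) over 8 libraries, for genes listed in both fractions. The largest called differences among coding genes were changes that were larger in cytoplasm. MACROD2 had 331 normalized reads in Epi against 45.0 in Mes in chromatin but 2361 against 7.21 in cytoplasm, a difference of 5.37 ± 0.41 (SE, n = 2 libraries per group) on the log2 scale with an adjusted p of 0.000395 by limma. TSTD1 differed by 5.31 ± 0.49 (SE), with 289 against 16.5 in chromatin and 955 against 0.537 in cytoplasm, and CRIP1 differed by 3.12 ± 0.61, with 209 against 5.28 and 1741 against 4.58. RCN3, a calcium-binding protein of the secretory pathway, was higher in Mes, at 589 normalized reads against 229.7 in chromatin and 2633 against 122 in cytoplasm, a difference of 3.08 ± 0.22. PCDHGA7, a clustered protocadherin gene, was higher in Mes at 326 against 25.0 in chromatin and 491 against 4.4 in cytoplasm, a difference of 2.87 ± 0.32. Changes that were larger in chromatin were those of ERC2 (2.37 ± 0.55, SE), TRAM1L1 (2.21 ± 0.53), the endoplasmic reticulum chaperone gene HSPA5 (1.78 ± 0.14), the growth factor binding protein gene IGFBP2 (1.58 ± 0.37) and COCH (1.56 ± 0.27), which were all higher in Epi. HSPA5 was 8.73 times higher in Epi in chromatin and 2.54 times in cytoplasm. Among non-coding genes J01415.5 went opposite ways by about as much in each fraction, a difference of 2.33 ± 0.29 (SE). The change was larger in chromatin for RRN3P2 (2.53 ± 0.31), higher in Epi, and for GAPDHP71 (4.52 ± 0.57), higher in Mes at 204 normalized reads against 0.408 in chromatin and 11.8 against 0.882 in cytoplasm. FABP5P7 and MAL2 had no read in Mes in either fraction, and PRKRIRP8 had none in Epi in cytoplasm. Their smaller change is therefore a lower bound, and their fitted differences do not show in which fraction the change was larger.

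Of 1529 coding genes in this model, 177 changed more in cytoplasm and 105 changed more in chromatin, and of 680 non-coding genes 45 changed more in cytoplasm and 43 changed more in chromatin (limma, adjusted p under 0.05). The excess in cytoplasm lay in coding genes higher in Mes, of which 110 changed more in cytoplasm and 27 in chromatin, whereas of those higher in Epi 67 changed more in cytoplasm and 78 in chromatin. In 7 and 2 of the called coding genes and in 14 and 25 of the called non-coding genes a line had no read in the fraction with the smaller change, so these calls do not show a larger change. The 45 also hold both non-coding genes that went opposite ways. With reads in both lines in both fractions, 25 non-coding genes changed more in cytoplasm and 9 in chromatin, and with a mean of at least 100 the numbers were 16 and 4. A pseudocount of 10 gave 362 and 159 coding genes and 92 and 126 non-coding genes. Of the 12 mesenchymal genes listed in both fractions, 4 changed more in cytoplasm and 2 changed more in chromatin, of 10 collagen and matrix genes 3 and 0, of 14 epithelial genes 1 and 3, and of 13 interferon-stimulated genes 2 and 0, and these small counts were not tested. Without the first Epi library of chromatin, 31 coding genes changed more in cytoplasm and 13 changed more in chromatin, and without the second Epi library of chromatin these numbers were 57 and 25. For non-coding genes they were 12 and 14 without the first and 18 and 19 without the second, and leaving out any other library gave from 27 to 44 and from 28 to 33. Leaving out a cytoplasm library gave between 88 and 108 and between 45 and 62 coding genes. The calls of CRIP1, ERC2, TRAM1L1, IGFBP2 and COCH ended without the first Epi library of chromatin. A library left alone in its group is assumed to vary like the other groups. The library numbers are arbitrary, because the group means carry none. Genes without reads in a group depend on the pseudocount, so their fitted differences are no bounds.

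Finally, levels were set side by side between fractions as ranks, without a test, because the tables were scaled separately. Across genes listed in both fractions the mean levels correlated with a Spearman rho of 0.89 for coding and 0.58 for non-coding genes. The non-coding value depended on the genes and means taken, with 0.21 at a mean of at least 100 in both fractions, 0.73 for Epi means alone and 0.75 for Mes means alone. Coding genes that ranked higher in chromatin included BLID, at percentile 67.6 in chromatin and 7.19 in cytoplasm, ADAM33 at 70.7 and 22.6, LY6G5B at 76.6 and 29.5, ANKRD18A at 76.2 and 32.4 and GNB3 at 76.5 and 32.8. Those that ranked higher in cytoplasm included C1orf233 at 22.6 in chromatin and 65.0 in cytoplasm, the histone gene HIST1H2BB at 15.6 and 51.9, UBE2L6 at 48.3 and 83.6, BEX1 at 18.2 and 53.4 and RBP7 at 41.3 and 75.3. Among non-coding genes BCYRN1, a small RNA of neuronal cytoplasm, ranked at percentile 27.6 in chromatin and 95.3 in cytoplasm, RPL31P2 ranked at 15.4 and 86.9, and LOC124685 ranked at 22.1 and 91.2. The pseudogenes PRKRIRP8, ADH5P3 and GAPDHP71 ranked at 72.8, 88.5 and 58.2 in chromatin and at 4.85, 34.6 and 6.47 in cytoplasm. These ranks pool both lines. With ranks by the means of each line alone, the 10 coding genes and 5 of the 6 non-coding genes named here kept the order of the fractions in both lines. The exception was GAPDHP71, at 6.18 in chromatin and 10.7 in cytoplasm in Epi and at 75.7 and 30.4 in Mes. The distances changed, as for BEX1, at 0.948 and 3.17 in Epi and 43.8 and 70.2 in Mes.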

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

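The result set out here is the difference of the change between fractions, tested by limma for genes listed in both. Differences are chromatin minus cytoplasm of the log2 change of Mes against Epi, so a negative value in a gene higher in Mes means a larger change in cytoplasm. The test of genes near 0 reads, the split of calls by direction, the medians at a minimum of 10 reads and the test for deletions among zinc finger genes with reads in Epi were chosen after the data were seen.

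38 named genes differed between the fractions by this test. Genes higher in Mes with a larger change in cytoplasm were RCN3 (-3.08), PCDHGA7 (-2.87), PIEZO2 (-2.62), FBLN2 (-2.51), HOXC-AS3 (-1.93), INHBB (-1.80), CD14 (-1.80), H19 (-1.65), SERPINE2 (-1.15), COL5A2 (-1.10), GREM1 (-0.85), TGFB2 (-0.82), PIM1 (-0.54) and NAV2 (-0.51). J01415.5 (-2.33) went opposite ways in the fractions, by about as much in each. Genes higher in Epi with a larger change in cytoplasm were MACROD2 (5.37), TSTD1 (5.31), CRIP1 (3.12), GALNT3 (2.34), FAM49A (2.23), IFI27 (2.19), XAF1 (2.02) and PVRL3-AS1 (1.78). Genes higher in Epi with a larger change in chromatin were RRN3P2 (-2.53), ERC2 (-2.37), TRAM1L1 (-2.21), HSPA5 (-1.78), IGFBP2 (-1.58), COCH (-1.56), CLDN1 (-1.34) and MMP2 (-0.82). GAPDHP71 (4.52), higher in Mes, had a larger change in chromatin. For FABP5P7 (3.50), MAL2 (2.76), PRKRIRP8 (2.54), PAX2 (-1.39), HOXC-AS5 (-1.80) and HOXC13 (-2.25) a line had no read in the fraction with the smaller change, so that change is a lower bound and no larger change in either fraction is shown. Of these 38 calls, 15 passed without each of the 8 libraries in turn and under every other setting in which the gene was tested at the same threshold. They were FABP5P7, FAM49A, FBLN2, GAPDHP71, HSPA5, IFI27, J01415.5, MACROD2, MAL2, PCDHGA7, PVRL3-AS1, RCN3, RRN3P2, SERPINE2 and TSTD1. The other 23 ended without at least 1 library. A library left alone in its group is assumed to vary like the other groups, and for FABP5P7 and MAL2 passing says nothing about the size of the change.

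More coding genes changed more in cytoplasm than in chromatin, 177 against 105, or 62.8% with an exact interval from 56.8% to 68.4%. The excess lay in genes higher in Mes, 110 against 27, and not in genes higher in Epi, 67 against 78. Genes close to 0 reads could give such a pattern, but among genes with at least 10 normalized reads in every library the share was 60.7% (exact interval from 54.7% to 66.5%), and 79.7% in those higher in Mes, which argues against the floor as the whole cause. A scaling difference between fractions would shift genes higher in Mes and genes higher in Epi by the same signed amount. The median difference was -0.31 in genes higher in Mes and 0.11 in genes higher in Epi, with bootstrap intervals from -0.37 to -0.25 and from 0.06 to 0.15, which argues against scaling alone. With at least 10 normalized reads in every library the medians were -0.23 and 0.05 (bootstrap intervals from -0.29 to -0.18 and from -0.02 to 0.09). All genes share the same 8 libraries, so the bootstrap intervals do not cover an error common to the genes of a library. A scaling difference as a part of the excess stays open, since at that minimum 40.4% of called genes higher in Epi (exact interval from 32.1% to 49.2%) changed more in cytoplasm. A difference between the lines in how transcripts are processed or kept after transcription remains an open hypothesis that these tables do not test.

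Some processed pseudogenes were listed beside their parent genes, 41 of 98 in cytoplasm and 20 of 123 in chromatin. In cytoplasm 41 listed processed pseudogenes had a listed parent of the same name and 39 of these pairs, 95.1% (exact interval from 83.5% to 99.4%), went the same way. The median distance of their log2 fold changes was 0.16, against 2.52 in random pairings with other coding genes, whose 5th percentile was 1.78. In chromatin 15 of 20 pairs, 75% (exact interval from 50.9% to 91.3%), went the same way, with a median distance of 0.48. Some pairs shared a parent, with 27 different parents in cytoplasm and 15 in chromatin. Pairs are therefore not independent, and the exact intervals may be too narrow. The cytoplasm values are consistent with reads shared between a pseudogene and its parent, so changes of such pseudogenes may be those of the parent. In chromatin the share was below the one set beforehand for shared reads, so no conclusion is drawn there. Pseudogenes without a listed parent are not covered. No biological explanation was tested.

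Coding genes with a ZNF symbol were mostly higher in Mes in chromatin, 57 against 7 in the rows used here, in which whole runs of ZNF numbers are absent. A deletion in the Epi line could remove such genes, but 38 of the 57 had an Epi mean of at least 10% of their Mes mean. For these genes this argues against a loss of all copies, provided that their Epi reads are not those of paralogs. A loss of some copies was not tested. For the 8 with 3 or fewer reads in Epi a deletion cannot be told apart from silencing, since only 1 of them had a listed neighbour with an Epi mean of 100 or more normalized reads. Reads shared among paralogs also remain open, since 43.9% of the 57 genes (exact interval from 30.7% to 57.6%) reached 10% of the Mes level of the strongest, ZNF91. A difference in the regulation of this gene family between the lines stays untested.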

How the results depend on the processing

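Tests on limma with the recovered libraries, on a minimum of 10 normalized reads in every library, on reads in both lines, on an adjusted p under 0.01 for the share of genes going the same way and against the tables' own shares were added after the data were seen. No paired analysis was possible because the recovered libraries carry no replicate number. TMM and RLE scaling, library totals, DESeq2, the count filters, joint fits of the tables or of 8 libraries for calls within a fraction, camera and fry, and replicate blocks were not run, since the files hold neither counts per sample nor uncalled genes.

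With a mean of at least 100 normalized reads, fewer genes remain by construction. In chromatin 527 coding genes were higher in Mes and 755 in Epi, and 251 and 266 non-coding genes. In cytoplasm 864 coding genes were higher in Mes and 758 in Epi, and 153 and 227 non-coding genes were higher in Mes and Epi. The epithelial group in chromatin then had an adjusted p of 0.0752, and no other tested group crossed the threshold at this minimum, at an authors' adjusted p under 0.01 or against the tables' own shares. Groups were not tested with libraries left out or with other pseudocounts. With limma on the recovered libraries and each library left out, non-coding genes in chromatin numbered between 596 and 646 higher in Mes and between 588 and 831 higher in Epi, and without the first or the second Epi library more were higher in Mes.

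For the difference between fractions, a pseudocount of 10 gave 362 coding genes with a larger change in cytoplasm and 159 in chromatin, and 92 and 126 non-coding genes. An adjusted p of 0.01 gave 47 and 23 coding and 11 and 11 non-coding genes. A log2 difference of at least 1 gave 98 and 43 coding genes. Limma without a trend gave 62 coding genes with a larger change in chromatin. A mean of at least 100 gave 16 and 4 non-coding genes, at least 10 in every library gave 20 and 9, and reads in both lines in both fractions gave 25 and 9. Leaving out each library gave from 31 to 206 and from 13 to 118 coding genes, and from 12 to 44 and from 14 to 33 non-coding genes. A stricter threshold lowers the counts by construction, whereas leaving out a library did not always lower them. For the pseudocount, the trend and the spread of counts among libraries, the cause was not tested.

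Directions and correlations of the change between fractions kept their sign at a mean of at least 100 and at an adjusted p under 0.01, the alternatives run on them. The rho of non-coding levels ranged from 0.21 at a mean of at least 100 to 0.75 for Mes means alone. Among named genes 442 values of the change between lines stayed past the threshold and 4 did not, in that GAPDHP71 and NR4A2 in cytoplasm and H19 and PCAT1 in chromatin had an authors' adjusted p above 0.01. For named genes 102 values of the difference between fractions fell short of the threshold, 34 newly passed it and 1145 stayed on their side, with no called difference changing sign. Chromatin libraries held fewer listed coding reads than cytoplasm libraries, which limits low genes there.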

Other observations

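The gene families, their tests and the kinds of non-coding gene here were chosen after the data were seen, so their p-values are not independent evidence, and the tests of neighbours and of antisense RNAs were set before their results were seen.

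Several gene families outside the fixed groups went largely one way, tested against all other listed genes by Fisher's exact test with adjustment over 20 tests. Members of a family are counted as independent here too, so these p-values are too small where members change together. Why a family went 1 way was not tested. A difference between the libraries of the lines in how RNA was recovered stays open. Histone genes numbered 47 in the chromatin tables, all higher in Epi (Fisher's exact test, adjusted p = 2.13e-11), and 13 in cytoplasm, again all higher in Epi (adjusted p = 0.000649). HIST1H3C and HIST1H2BE were higher in Epi by 6.03 and 5.80 on the log2 scale in chromatin in the authors' deposited table. Clustered protocadherin genes, which encode cell surface adhesion proteins of neurons, numbered 18 in chromatin and 19 in cytoplasm, all higher in Mes (adjusted p = 1.44e-06 and 3.78e-06), and their overlapping exons can share reads. Coding genes with a ZNF symbol numbered 57 against 7 in chromatin and 48 against 8 in cytoplasm, higher in Mes (adjusted p = 4.63e-13 and 4.13e-08). The non-coding tables held another 12 ZNF symbols higher in Mes and 2 higher in Epi in chromatin and 11 and 2 in cytoplasm, pseudogenes and antisense RNAs among them. These counts cover the rows used here, in which whole runs of ZNF numbers are absent from the coding tables. Small nucleolar RNAs numbered 20 in chromatin, all higher in Epi (adjusted p = 4.08e-05), and 1 higher in Mes against 4 higher in Epi in cytoplasm (adjusted p = 0.396). UDP-glucuronosyltransferase and cytochrome P450 genes numbered 4 higher in Mes and 12 higher in Epi in chromatin (adjusted p = 0.242) and 3 and 10 in cytoplasm (adjusted p = 0.125). X-linked germline genes numbered 1 and 2 in chromatin and 0 and 4 in cytoplasm (adjusted p = 1 and 0.157).

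Metabolic and stress genes also took sides. All 16 listed genes of the response to amino acid starvation were higher in Epi in chromatin and 12 of 13 in cytoplasm (Fisher's exact test, unadjusted p = 0.000141 and 0.00357). The group as first drawn up also held DDR2, a collagen receptor gene that is not of this response, and then had 17 of 17 and 13 of 14 (adjusted p = 0.000217 and 0.00322). The cystine transporter gene SLC7A11 and the asparagine synthetase gene ASNS were higher by 4.82 and 4.12 on the log2 scale in chromatin in the authors' deposited table. Cytosolic aminoacyl-tRNA synthetase genes numbered 8 in chromatin and 7 in cytoplasm, all higher in Epi (adjusted p = 0.0179 and 0.0227). Glycolysis and hypoxia genes numbered 9 in chromatin, all higher in Mes, and 13 against 1 in cytoplasm (adjusted p = 0.00121 and 0.00137), with EGLN3 and CA9 higher in Mes by 4.23 and 2.81 on the log2 scale in chromatin in the authors' deposited table. Endoplasmic reticulum chaperone and unfolded protein response genes numbered 15 higher in Epi against 1 higher in Mes in chromatin (Fisher's exact test, p = 0.00178, adjusted p = 0.00322) and 6 against 2 in cytoplasm (adjusted p = 0.323). This group was drawn up after members were seen to be higher in Epi, so its test lends no support to a hypothesis that the response was more active in the Epi cultures, which stays untested.

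Of 6 kinds of non-coding gene compared between the tables, 3 differed in their share. The test counts the tables as independent, although 680 genes are in both. The shares are those of genes called between the lines in each fraction, and not of all genes found there. MicroRNA genes made up 3.92% of the chromatin table (65 genes) and 0.849% of the cytoplasm table (9 genes), and transcripts named as intronic to a host gene made up 1.02% (17 genes) and 0.0943% (1 gene) (Fisher's exact test, adjusted p = 2.19e-06 and 0.00776). Antisense RNAs named after a gene were 3.37% in chromatin (56 genes) and 5.19% in cytoplasm (55 genes; adjusted p = 0.0443), nearly equal numbers in tables of unequal length. LINC-named RNAs (36 and 31 genes, adjusted p = 0.304) and small nucleolar RNA genes (20 and 5 genes, adjusted p = 0.094) did not pass the test. Most names in these tables were clone names, 71.0% and 69.4% (adjusted p = 0.389).

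A hypothesis that neighbouring genes change together was tested on coding genes that are next to each other in the RefSeq gene order. In chromatin 87.9% of 365 pairs of listed neighbours went the same way, against a median of 51.8% when directions were permuted 10000 times (one-sided permutation p = 0.0001, the smallest these permutations can give). Without zinc finger, protocadherin, HOX, UGT, keratin and histone genes the share was 85.7% of 300 pairs, against 52.3%, and in cytoplasm it was 81.5% of 379 pairs, against 49.9% (permutation p = 0.0001 for each). The pattern may come from regions that differ as a whole between the lines, in copy number or in chromatin state, and these were not told apart here. Reads shared between neighbours also stay open, since the strand used in counting is not given. Related genes outside the families left out were kept in the pairs.

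Antisense RNAs were compared with the gene they are named after. A host gene was listed for 11 of the 50 antisense RNAs taken in chromatin and 11 of 51 in cytoplasm. For intronic transcripts in chromatin it was 7 of 17. Some antisense RNAs, such as ELOVL2-AS1 and FLG-AS1, are in the pairs of both fractions, so these counts are not independent. In chromatin 10 of 11 antisense RNAs with a listed host gene, 90.9% (exact interval from 58.7% to 99.8%), went the way of the host (two-sided exact binomial test, p = 0.0117, adjusted p = 0.0156), as did 10 of 11 in cytoplasm and 7 of 7 intronic transcripts in chromatin (exact binomial test, p = 0.0156). Shared regulation is consistent with this, and so is the counting of host reads for the partner, since the strand used in counting is not given in the sources used here.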
